A study of Mus musculus with 12 samples.

How the data were processed

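The series holds 12 libraries of polyadenylated RNA from mouse thymus, read as paired ends of 75 bases. Per the labels, 9 libraries are T cell acute lymphoblastic leukemias in the thymus of mice that carry a tetracycline-inducible form of the interleukin-7 receptor alpha chain (Il7r), and 3 libraries are thymus of healthy control mice. The labels give the strain as F5. RNA was extracted with Trizol per the labels' protocols. The labels number the libraries within each group and do not say whether each came from a separate animal, so the p-values measure only the spread between these samples, which may be partly technical.

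For each library the authors deposited kallisto estimated counts, one value per transcript, together with the transcript's length and effective length, per the file headers. The authors also deposited transcripts-per-million (TPM) values in the same files, scaled to the same sum in each library, per the file headers. The submitters' processing notes name kallisto, FastQC and the mouse genome build mm10. Their versions and the annotation release behind the transcript index are not given in the sources used here. Each file lists the same 128622 transcripts of 51826 genes, and gene coordinates were taken from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, which holds 51633 of these genes by identifier. kallisto divides reads shared by near-identical transcripts among them, so single values of paralogs, pseudogenes and overlapping or antisense genes are uncertain.

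Estimated counts were summed over the transcripts of a gene and rounded to whole numbers. Library totals ran from 8133152 to 12019924 estimated counts in the controls and from 11617724 to 34769946 in the tumors. The counts-per-million (CPM) values in the text are scaled by the trimmed mean of M-values (TMM) factors. Before this scaling 1 count stood for 0.0832 to 0.123 CPM in a control and 0.0288 to 0.0861 CPM in a tumor. The 95% Wilson interval of any percentage of a library's counts given below reached at most 0.0326 percentage points to either side, except for T cell receptor segments, which have their own intervals. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

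Tumors were compared with controls by edgeR's quasi-likelihood F test with TMM factors and filterByExpr by group, which left 40521 genes, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. The fold changes have tumor over control as their direction. Il7r was also tested by a two-sided exact permutation test of log2(CPM + 1) over the 220 splits of 12 libraries into 9 and 3, where the smallest possible p is 0.00455. The same exact test was used for the percentage taken by the largest T cell receptor V segment, separately for the 35 Trbv and 128 Trav segments, with Benjamini-Hochberg adjustment over both. Gene lists and chromosomes were tested with camera in limma on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 35 lists or over the chromosomes. Camera compares the genes of a list with all other tested genes. Each list was tested again with a correlation estimated from the data, in the edgeR fit of all 12 libraries only and not in the alternatives.

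The 35 lists covered interleukin-7 receptor and JAK-STAT parts, STAT5-induced genes, PI3K-AKT-mTOR parts, FOXO-induced genes, Notch receptors and induced genes, MYC-induced growth genes, G1-S genes and G2-M genes. They also covered cell cycle inhibitors and p53-induced genes, the BCL2 family, glycolysis, cholesterol and fatty acid synthesis, ATF4-induced genes, interferon-induced genes, and immediate-early and heat shock genes. T lineage lists covered T cell identity, double-positive thymocytes, mature single-positive thymocytes, early progenitors, T-ALL oncogenes, T-ALL tumor suppressors, cytotoxic genes, inhibitory receptors and regulatory T cells. Markers of other cells covered B cells, macrophages, dendritic cells, neutrophils, erythroid cells, thymic epithelium, fibroblasts, endothelium, adipocytes and NK cells, and a last list held sex-linked transcripts. Some lists share members, such as Il2ra, which stood in 5 of them.

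The tests, the gene lists, the alternatives and the rule for genes named in the text were chosen before the data were examined, except for the alternatives and tests said in the closing section to have been chosen later. The rule named Il7r, the 12 protein-coding genes with the largest fold change in each direction among those past the threshold with at least 5 CPM on average and no overlap between groups, and in each list up to 4 members past the threshold or otherwise the 2 with the highest mean CPM. It also named T-ALL oncogenes at 5 CPM or more in any tumor and at least 8 times the highest control, and 19 genes of cytokine signaling, Notch signaling, cell cycle and thymocyte development whatever their result. This gave 83 genes, none by the part on genes past the threshold. Of these, 4 are not reported here, and counts over named genes cover the other 79, of which 62 came through the lists. Other genes in the text were chosen after their values were seen and are described so.

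The background of each library was measured, after its composition was seen, as the median CPM per kilobase of exon, without TMM factors, over 1415 olfactory and vomeronasal receptor genes (Olfr, Vmn1r and Vmn2r), which thymocytes are not known to express. Other shares of each library were taken over mitochondrial genes, over 12 gene models made largely of satellite-like repeats and over 80 ribosomal protein genes. A library whose receptor median was above 0.5 CPM per kilobase was treated as of high background, which gave the 3 controls and tumors 7 to 9. This division follows a technical measure and is not one of the study's groups.

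The alternatives fixed in advance were DESeq2, relative log expression (RLE) factors, library totals only, no filter on low counts, a stricter filter of 1 CPM in 9 libraries, offsets for effective length, voom weights per group, protein-coding genes only, limma on log2(TPM + 1) or log2(TPM + 0.1) for genes at 1 TPM or more in 3 libraries, a fit with the replicate number as a block, and each library left out in turn. Alternatives added after seeing the data were a fit without tumors 7 to 9, tumors 7 to 9 against the controls, the background as a covariate, and nuclear protein-coding genes with a name only. In counts simulated for 9 against 3 libraries over the same 40521 genes, with 200 changed genes and a dispersion of 0.1, the edgeR step recovered 17% of changes of 2-fold and 91% of changes of 4-fold, with 2 false calls. At the dispersion of the real fit, 0.687, it recovered 0% of either size, with 0 false calls by edgeR. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.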

Results

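Polyadenylated RNA was measured in 12 mouse thymus libraries. Of these, 9 came from T cell leukemias that arose in the thymus of mice with an inducible interleukin-7 receptor alpha chain, and 3 from thymus of healthy mice. Totals were 12019924, 8726703 and 8133152 estimated counts in controls 1 to 3. Those of tumors 1 to 9 were 24536073, 21845948, 20667250, 25982735, 34769946, 18431516, 17158731, 13606573 and 11617724.

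The libraries differed in what they were made of, and this difference followed the groups in part. All controls lay with tumors 7 to 9, apart from tumors 1 to 6. A comparison of tumors with controls is therefore also, in part, a comparison of these compositions. In tumors 1 to 6, 31.6% to 69.3% of the counts fell on mitochondrial genes and 0.115% to 2.43% on 12 gene models made largely of satellite-like repeats. In the controls and in tumors 7 to 9, the mitochondrial part was 0.0948% to 11.1% and the satellite-like part 29.8% to 59.4%. Messenger RNA of 80 ribosomal protein genes, which every cell expresses, took 0.330% to 1.27% of the counts in tumors 1 to 6. It took 0.104% to 0.252% in the controls and 0.0474% to 0.0735% in tumors 7 to 9. Olfactory and vomeronasal receptor genes, which thymocytes are not known to express, had a median of 1.55 to 1.99 CPM per kilobase in the controls and 0.643 to 1.76 in tumors 7 to 9, against 0 to 0.136 in tumors 1 to 6. At least 1 count was seen for 98.9% to 99.4% of these receptor genes in the controls and tumors 7 to 9, and for 46.9% to 94.0% in tumors 1 to 6.

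**Figure D1:**
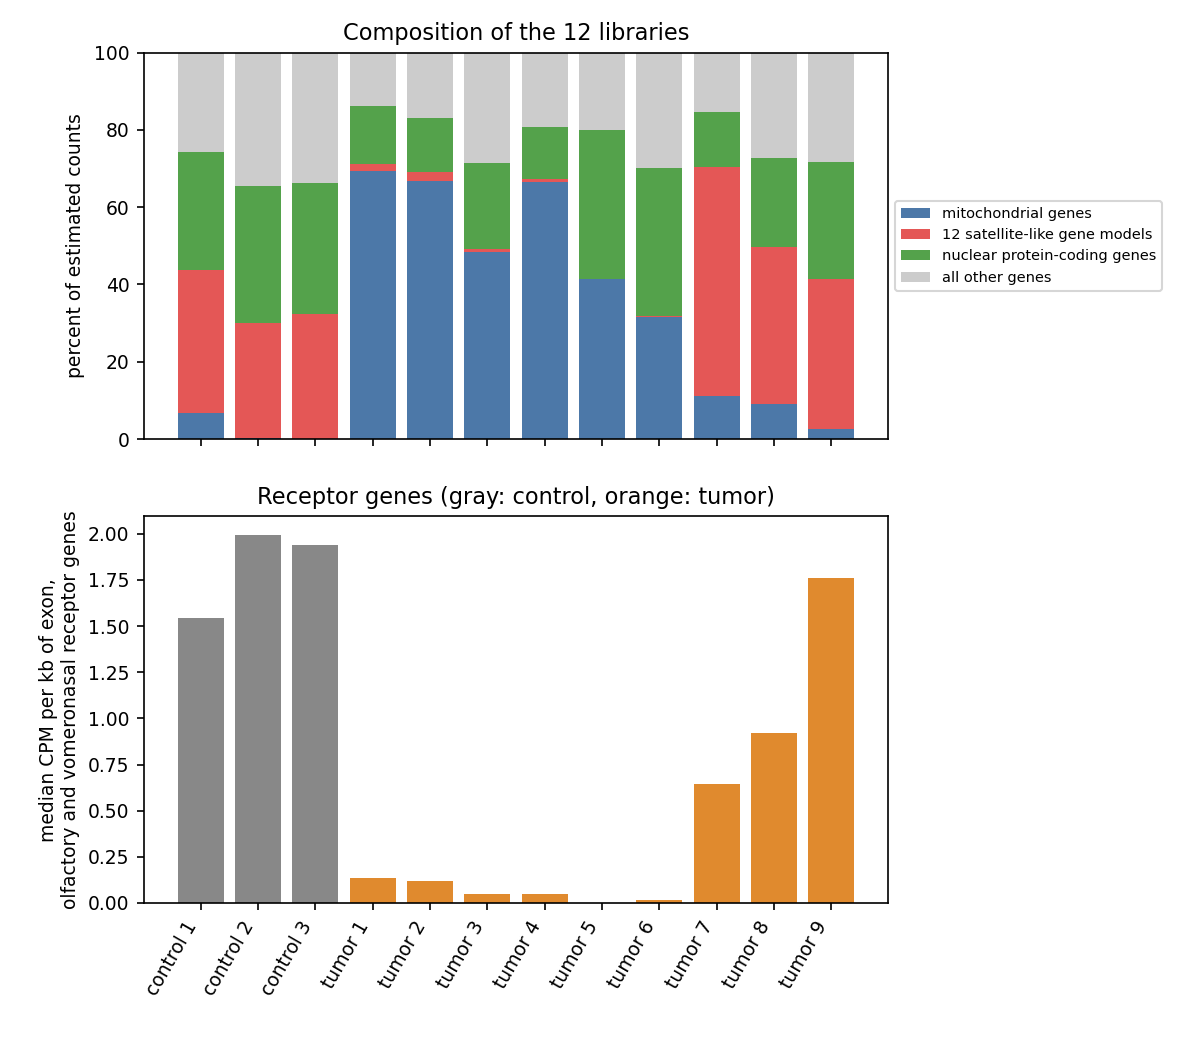
The upper plot shows the percentage of estimated counts in each of the 12 libraries that fell on mitochondrial genes, satellite-like gene models, nuclear protein-coding genes and all others. The lower plot shows the median CPM per kilobase of exon of 1415 receptor genes; controls (gray) and tumors 7 to 9 lie between 0.643 and 1.99, and tumors 1 to 6 between 0 and 0.136.

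The first comparison asked whether the induced gene was higher in the tumors. Il7r (ENSMUSG00000003882, mm10 chromosome 15, 9505788 to 9530176, minus strand) encodes the alpha chain of the interleukin-7 receptor, which carries survival signals in thymocytes. Its level was 2.92 ± 0.356 CPM (SD, n = 3) in the controls and 124 ± 173 CPM (SD, n = 9) in the tumors. In the controls Il7r lay at 0.874 to 1.09 times the median density of the receptor genes. The control value is thus at the background and does not measure Il7r messenger RNA of healthy thymus. Tumor 3 held 511 CPM, tumor 2 held 308, and tumors 1, 4, 5 and 6 held 72.9, 78, 97.6 and 33.3. Tumors 7 to 9 held 5.03, 5.50 and 5.63 CPM. The estimated counts behind these values were 75 to 88 in the controls, 522 to 4151 in tumors 1 to 6 and 87 to 168 in tumors 7 to 9. Only 1 transcript of Il7r, Il7r-201 of 3208 bases, was quantified, so these counts say nothing of its transcript forms. Whether they came from the inducible form or from the mouse's own gene was not tested.

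With TMM or RLE factors all 9 tumors lay above the highest control for Il7r, and with library totals or TPM 7 did, tumors 7 and 8 being the exceptions. On TMM-scaled values the two-sided exact permutation test gave p = 0.0318 for a difference of 3.54 in log2(CPM + 1). That p became 0.0545 when any one of controls 1, 2 or 3 was left out, 0.105 with scaling by library totals, where the difference was 1.74, and 0.177 on log2(TPM + 1), where it was 1.03. In the edgeR fit the log2 fold change was 5.41 with a standard error of 1.61 and an adjusted p of 0.129. Without tumors 7 to 9 it was 5.56 with an adjusted p of 2.75e-04, in a range of 2.66e-08 to 1.00 over all alternatives. The fit without tumors 7 to 9 sets tumors of low background against controls of high background, so it cannot part the groups from the background.

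**Figure D2:**
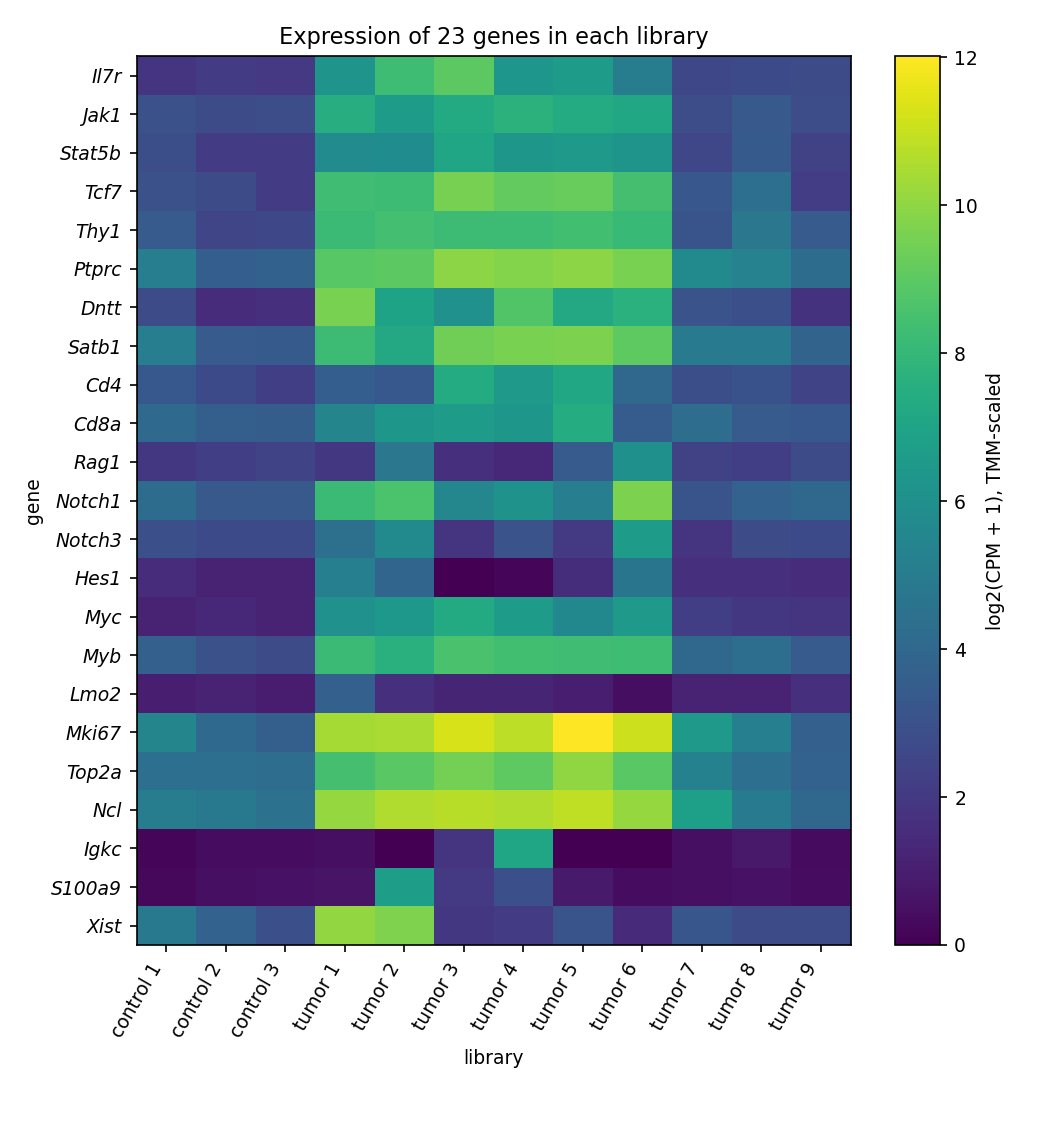
Each tile is log2(CPM + 1) of a gene (vertical axis) in a library (horizontal axis), with TMM-scaled CPM and darker color for lower values. Il7r reaches 511 CPM in tumor 3, and Mki67 is 1350 to 4141 CPM in tumors 1 to 6 and 11.4 to 90.6 CPM in all other libraries.

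The second comparison asked which genes and gene groups set the tumors apart from healthy thymus. Tcf7, a transcription factor of the T lineage, was at 299 to 748 CPM in tumors 1 to 6, 3.55 to 19.7 CPM in tumors 7 to 9 and 5.46 ± 1.84 CPM (SD, n = 3) in the controls. Mki67, a marker of dividing cells, was at 1350 to 4141, 11.7 to 90.6 and 23.5 ± 16.9 CPM (SD, n = 3) in the same order. Of 35 gene lists, 20 rose in the tumors relative to all other genes by camera, 0 fell and 15 did not pass, and none of the 20 held with an estimated correlation, whose smallest adjusted p was 0.314. With the background as a covariate, where the median of all genes was 0.36, 2 lists rose relative to the other genes, early progenitors and oncogenes, and 5 fell, namely glycolysis, G2-M, G1-S, cholesterol synthesis and PI3K parts. STAT5-induced, mature single-positive, interferon-induced and macrophage genes did not pass with library totals or with limma on either log2 TPM scale. Cholesterol synthesis and the BCL2 family did not pass on either TPM scale, nor glycolysis on log2(TPM + 1), and the interferon-induced and macrophage lists did not under the stricter filter. With library totals the medians of 11 of these 20 lists lay below 0 and all 20 above the median of all genes.

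No gene was higher in the tumors past the threshold in the edgeR fit of 40521 genes, and 2 were lower, with 7298 genes at an unadjusted p below 0.05. DESeq2 called 4084 higher and 53 lower, with neither of those 2 genes among the 53, as it gave them no adjusted p. Limma with voom weights per group called 6914 higher and 8111 lower, and limma on log2(TPM + 1) called 126 higher and 34628 lower. Without tumors 7 to 9, edgeR called 7562 higher and 7823 lower, and 687 of 1391 tested receptor genes were among the lower ones. The 2 genes called lower by edgeR, chosen after their values were seen, were Gm3147 (chromosome 5, 94612069 to 94616342, minus strand) and A430089I19Rik (chromosome 5, 94302519 to 94306796, minus strand). Gm3147 had 50, 69 and 85 counts in the controls, 1 count in tumor 4 and 0 in the 8 other tumors; A430089I19Rik had 45, 103 and 53, with 1 count in tumor 4 and 0 in the others. Both had an adjusted p of 0.0118, a test that does not separate expression from a difference in the genome of the mice. That call was lost when control 2, control 3 or tumor 1, 2, 4 or 7 was left out, which left 0 genes lower, and 3 were lower without control 1 or tumor 8. The median log2 fold change of all tested genes was -0.45, and it was -0.72 with RLE factors and -1.83 with library totals, so directions of single genes are relative to the scaling. TMM factors were 2.52 to 3.16 in the controls, 0.282 to 0.852 in tumors 1 to 6 and 1.01 to 2.58 in tumors 7 to 9.

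Members of the lists that rose did not pass over all genes tested, where 0 of 391 were called by edgeR, and the counts that follow are adjusted over the list alone. Among protein-coding genes only, 12 lists rose, so that 8 of the 20 rising lists lost their call. The B cell and erythroid lists fell there, with medians of -0.94 and -1.08. In tumors 7 to 9 against the controls, a comparison added after the data were seen, edgeR called 9 genes higher and 9 lower. There the tumor suppressor list rose by a median of 0.43, T cell identity by 0.50, immediate-early and heat shock genes by 0.47 and oncogenes by 0.42 (camera adjusted p = 1.58e-04, 0.00138, 9.07e-04 and 9.07e-04), and glycolysis fell, with a median of -0.52 (adjusted p = 3.24e-04). These list calls used the preset correlation only. The glycolysis gene Gapdh was at 7.16, 25.7 and 16.4 CPM in controls 1 to 3 and 6.94 to 8.80 CPM in tumors 7 to 9. Control 1 thus lay with these tumors for Gapdh. Ribosomal protein genes also took a smaller share in tumors 7 to 9, so a lower level there was not particular to glycolysis. Actb, a cytoskeletal actin of every cell type, chosen after its values were seen, lay at 724 to 1215 CPM in tumors 1 to 6, 7.28 to 52.0 in tumors 7 to 9 and 11.9 on average in the controls.

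The T cell identity list had the highest median of the 35. All 21 tested members of the T cell identity list were higher, adjusted over the list alone, and the list rose with a median log2 fold change of 3.86 (camera adjusted p = 8.81e-15; adjusted p = 0.314 with an estimated correlation). Thy1, a T cell surface protein, was at 283 to 341 CPM in tumors 1 to 6, 7.69 to 26.4 CPM in tumors 7 to 9 and 6.60 ± 2.85 CPM (SD, n = 3) in the controls. Ptprc, the leukocyte phosphatase CD45, was at 480 to 986, 18.0 to 52.4 and 19.2 ± 13.1 CPM (SD, n = 3). The double-positive thymocyte list rose as well, by a median of 2.59, with 9 of 18 members higher, adjusted over the list alone (adjusted p = 1.3e-07; 0.314 as the adjusted p with an estimated correlation). Dntt, which adds bases at receptor gene joints, was at 66.4 to 763 CPM in tumors 1 to 6, 2.41 to 7.51 CPM in tumors 7 to 9 and 3.27 ± 2.28 CPM (SD, n = 3) in the controls. Satb1, a chromatin organizer of thymocytes, was at 150 to 794, 13.1 to 30.1 and 18.0 ± 14.3 CPM (SD, n = 3). The list of mature single-positive thymocytes rose by 1.15 with 0 of 18 members called by edgeR, adjusted over the list alone (adjusted p = 0.00409; adjusted p = 0.377 with an estimated correlation). Without tumors 7 to 9 the medians of the T cell identity, double-positive and mature single-positive lists were 4.14, 2.75 and 1.15. Ribosomal protein genes had 3.80 in that fit, so these rises cannot be told apart from low messenger RNA signal in the controls. Early progenitor genes did not pass, with a median of -0.38 over 17 members (adjusted p = 0.700), but rose with the background as a covariate, with a median of 0.77 (adjusted p = 0.00444). Cd34 was at 4.99 to 29.3 CPM in tumors 1 to 6, 38.5 to 43.4 CPM in tumors 7 to 9 and 38.9 ± 3.36 CPM (SD, n = 3) in the controls.

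The interleukin-7 receptor and JAK-STAT list rose by a median of 2.07, with 10 of 15 members higher, adjusted over the list alone (camera adjusted p = 5.29e-06; adjusted p = 0.314 with an estimated correlation). Jak1, a kinase bound to the receptor, was at 99.3 to 211 CPM in tumors 1 to 6, 6.07 to 9.23 CPM in tumors 7 to 9 and 6.34 ± 0.532 CPM (SD, n = 3) in the controls. Stat5b, which the kinases activate, was at 54.9 to 133, 4.02 to 9.69 and 4.32 ± 1.75 CPM (SD, n = 3). The list of STAT5-induced genes rose by 0.60, with 4 of 19 members higher, adjusted over the list alone (adjusted p = 0.00426; adjusted p = 0.314 with an estimated correlation). Cish and Socs2, which restrain cytokine signals, had log2 fold changes of -1.18 and -0.45 with adjusted p of 0.428 and 0.684 by edgeR, and both were lower in the fit without tumors 7 to 9, at -2.01 (adjusted p = 0.0319) and -1.62 (adjusted p = 0.00293). The median of all genes was -1.29 in that fit, and in the controls Cish lay at 1.03 to 1.90 and Socs2 at 1.40 to 2.20 times the median density of the receptor genes. Bcl2, a survival gene, was at 7.94 to 18.7 CPM in the 9 tumors and 6.87 ± 0.790 CPM (SD, n = 3) in the controls. Its log2 fold change was 0.78 with an adjusted p of 0.458 by edgeR, and -1.07 with library totals. In the controls Bcl2 lay at 1.05 to 1.36 times the median density of the receptor genes. The BCL2 family rose by 1.36 with 0 of 17 members called by edgeR, adjusted over the list alone (adjusted p = 8.35e-04; adjusted p = 0.314 with an estimated correlation). Without tumors 7 to 9 the medians of the JAK-STAT, STAT5-induced and BCL2 lists were 2.15, 0.60 and 1.41. Ribosomal protein genes, which every cell expresses, had 3.80 in that fit. The rises of these lists thus cannot be told apart from low messenger RNA signal in the controls.

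PI3K-AKT-mTOR parts and FOXO-induced genes rose, by medians of 1.89 and 2.14 (adjusted p = 5.45e-09 and 3.91e-06; adjusted p = 0.316 and 0.314 with an estimated correlation). Adjusted over the list alone, 13 of 25 and 9 of 16 members were higher. Rictor, a part of mTOR complexes, was at 58.8 to 155 CPM in tumors 1 to 6, 7.57 to 8.79 CPM in tumors 7 to 9 and 7.37 ± 0.333 CPM (SD, n = 3) in the controls. Notch receptors and induced genes rose by 1.45, with 3 of 16 members higher, adjusted over the list alone (adjusted p = 0.00362; adjusted p = 0.316 with an estimated correlation). Medians of the PI3K, FOXO and Notch lists were 2.05, 2.27 and 1.57 without tumors 7 to 9, where ribosomal protein genes had 3.80. These rises too cannot be told apart from low messenger RNA signal in the controls.

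MYC-induced growth genes rose by a median of 3.40, G1-S genes by 3.14 and G2-M genes by 3.21 (adjusted p = 3.1e-13, 4.22e-11 and 6.72e-12; adjusted p = 0.314, 0.316 and 0.314 with an estimated correlation). Higher members, adjusted over the list alone, numbered 21 of 24, 18 of 22 and 20 of 21. Without tumors 7 to 9 the medians were 3.62, 3.39 and 3.52. Ribosomal protein genes, which every cell expresses, had a median of 3.80 in that fit. The rises of these lists thus cannot be told apart from low messenger RNA signal in the controls. Ncl, a nucleolar protein, was at 1105 to 1837 CPM in tumors 1 to 6, 15.6 to 107 CPM in tumors 7 to 9 and 27.6 ± 5.27 CPM (SD, n = 3) in the controls. Top2a, which untangles DNA in dividing cells, was at 355 to 1037, 12.7 to 38.3 and 19.6 ± 0.953 CPM (SD, n = 3). Cell cycle inhibitors and p53-induced genes rose by 1.06, with 4 of 18 members higher, adjusted over the list alone (adjusted p = 8.35e-04; adjusted p = 0.314 with an estimated correlation). Cdkn2a, an inhibitor often lost in T cell leukemia, was at 0.462 to 1.76 CPM in the tumors and 0.365 to 0.567 CPM in the controls.

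Metabolic and stress groups also rose. Glycolysis genes rose by a median of 1.80 (adjusted p = 4.67e-05; adjusted p = 0.445 with an estimated correlation) and cholesterol and fatty acid synthesis by 1.13 (adjusted p = 2.73e-05; adjusted p = 0.377 with an estimated correlation), with 0 of 19 and 0 of 23 members called by edgeR, adjusted over the list alone. Gapdh, a glycolytic enzyme, was at 78.5 to 248 CPM in tumors 1 to 6, 6.94 to 8.80 CPM in tumors 7 to 9 and 16.4 ± 9.25 CPM (SD, n = 3) in the controls. ATF4-induced genes rose by 2.53, with 12 of 18 higher, and immediate-early and heat shock genes by 2.59, with 11 of 18 higher, adjusted over the list alone (adjusted p = 6.33e-06 and 9.21e-06; adjusted p = 0.314 for both with an estimated correlation). Interferon-induced genes rose by 0.71, with 0 of 19 called by edgeR, adjusted over the list alone (adjusted p = 0.0209; adjusted p = 0.539 with an estimated correlation). That call was lost without tumor 4 and without tumors 7 to 9, where the adjusted p was 0.0899. In the fit without tumors 7 to 9 the medians were 2.07 for glycolysis and 1.26 for cholesterol and fatty acid synthesis. They were 2.76 for ATF4-induced genes and 2.76 for immediate-early and heat shock genes, against 3.80 for ribosomal protein genes. Low messenger RNA signal in the controls thus cannot be told apart from these rises.

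Of the leukemia gene lists, tumor suppressors rose and oncogenes did not pass. Without tumors 7 to 9 the median was 3.60 for tumor suppressors and -1.06 for oncogenes. Ribosomal protein genes, which every cell expresses, had 3.80 in that fit, and all tested genes -1.29. The rise of tumor suppressors thus cannot be told apart from low messenger RNA signal in the controls. Tumor suppressors had a median of 3.34, and 23 of 27 were higher, adjusted over the list alone (adjusted p = 1.12e-15; adjusted p = 0.314 with an estimated correlation); 4 of them, Ptprc, Gata3, Lef1 and Bcl11b, also stand in the T cell identity list. Oncogenes had a median of -0.04 and a mean of 0.82 (adjusted p = 0.335; with the background as a covariate a median of 1.02 and an adjusted p of 3.14e-04), with 3 of 22 higher, adjusted over the list alone. Myc, a driver of growth, was at 48.2 to 160 CPM in tumors 1 to 6, 2.48 to 3.64 CPM in tumors 7 to 9 and 1.40 ± 0.211 CPM (SD, n = 3) in the controls. Myb, a transcription factor of immature blood cells, was at 199 to 383, 10.1 to 19.4 and 8.14 ± 3.11 CPM (SD, n = 3).

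Markers of other cell types passed in 1 list, that of macrophages, which rose by a median of 0.88 with 0 of 17 members called by edgeR, adjusted over the list alone (adjusted p = 0.0325; adjusted p = 0.664 with an estimated correlation). It was lost without control 2, without tumor 1, 2 or 9, with DESeq2, RLE factors or library totals, and without tumors 7 to 9, where the adjusted p was 0.0955. Medians were -0.55 for B cells (adjusted p = 0.560), -0.05 for dendritic cells (0.210), 0.37 for neutrophils (0.848), -0.83 for erythroid cells (0.13) and -0.22 for thymic epithelium (0.782). They were 0.23 for fibroblasts (adjusted p = 0.508), -0.76 for endothelium (0.560), -0.65 for adipocytes (0.508) and -0.46 for NK cells (0.926). Cytotoxic genes had 0.10 (adjusted p = 0.57), inhibitory receptors 0.20 (0.411), regulatory T cell genes 0.28 (0.331) and sex-linked transcripts 2.43 (0.341). Adjusted over the list alone, 4 of 15 dendritic cell genes, and 1 each of the regulatory T cell, fibroblast, endothelial and NK lists, were higher. Mean and median had opposite signs for oncogenes, B cells, dendritic cells, thymic epithelium and NK cells, and camera gave the direction of the mean for oncogenes, dendritic cells and thymic epithelium. Gzma, the protease granzyme A, was at 18.6 to 405 CPM in tumors 1 to 6, 0.931 to 3.24 CPM in tumors 7 to 9 and 1.71 ± 1.62 CPM (SD, n = 3) in the controls.

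Single genes of Notch signaling and of thymocyte stages had wide ranges over tumors 1 to 6. Notch1 was at 809 CPM in tumor 6, 393 in tumor 2 and 289 in tumor 1, and at 34.0 to 71.1 CPM in tumors 3 to 5. Notch3 was at 99.0, 53.6 and 20.6 CPM in tumors 6, 2 and 1 and at 2.59 to 7.36 CPM in tumors 3 to 5. Hes1, a gene induced by Notch, was at 24.3, 14.1 and 35.8 CPM in tumors 6, 2 and 1, 0.136 CPM in tumor 4, 1.99 CPM in tumor 5 and 0 counts in tumor 3. Nrarp, also induced by Notch and chosen after its values were seen, was at 4.68 CPM in tumor 2. It was at 0 to 1.48 CPM in the 5 others, tumor 6 at 0, with 0 to 36 counts over tumors 1 to 6. Dtx1, Heyl and Igf1r, linked to Notch and chosen after their values were seen, were higher in tumors 1, 2 and 6. Dtx1 was at 16.5 to 39.2 CPM there and 0.439 to 5.59 CPM in tumors 3 to 5. Igf1r was at 28.5 to 178 and 8.62 to 24.1 CPM. Heyl, at 3.43 to 8.85 CPM there, was lower in tumors 3 to 5. Cdk6, of the Notch list, did not follow them, at 143 to 496 CPM there and 456 to 499 CPM in tumors 3 to 5. Cd4 was at 169, 88.2 and 146 CPM in tumors 3 to 5 and 8.85 to 15.5 CPM in tumors 1, 2 and 6. Cd8a was lowest in tumor 6, at 10.1 CPM, and at 43.0 to 175 CPM in tumors 1 to 5. Rag1, which cuts receptor genes, was at 65.2 CPM in tumor 6 and 26.2 CPM in tumor 2, with 1.64 to 10.1 CPM in the 4 others. Ikzf2, the Helios transcription factor, was at 322 to 393 CPM in tumors 3 to 5 and 61.5 to 68.7 CPM in tumors 1, 2 and 6. Lmo2, an oncogene of early progenitors, was at 11.7 CPM in tumor 1 and 0.382 to 2.21 CPM in the 8 other tumors. No label divides the tumors, so no test was made between them, and other genes of these groups need not share these ranges.

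The third comparison asked whether single T cell receptor V segments dominated the tumors. The largest Trbv segment took 53.3% ± 26.9 (SD, n = 9) of Trbv counts in the tumors and 27.3% ± 3.10 (SD, n = 3) in the controls, a difference of 26.0 percentage points (exact permutation p = 0.173, adjusted 0.345). Trbv16 was the largest segment in all 3 controls and in tumors 2, 3, 5, 6, 7 and 9. It took 93.2% (95% Wilson interval 89.8% to 95.6%) of 295 counts in tumor 5 and 82.8% (75.3% to 88.4%) of 128 counts in tumor 3. Trbv19 led in tumor 4 with 62.4% (58.5% to 66.3%) and Trbv13-2 in tumor 1 with 50.04% (44.6% to 55.4%). In tumors 7 to 9 the largest segment took 16.6% to 24.9%. Without tumors 7 to 9 the difference was 41.8 percentage points with an exact permutation p of 0.0119, the smallest possible with 84 splits. That comparison sets tumors of low background against controls of high background, and the high-background tumors lay below the controls, so it cannot part the groups from the background. For Trav it gave 19.3 percentage points with an exact permutation p of 0.179. Trav6-1 was the largest Trav segment in every library except tumor 3, where Trav7d-2 took 39.0% (35.6% to 42.5%). The largest Trav segment took 35.3% ± 23.8 (SD, n = 9) in the tumors and 25.5% ± 5.54 (SD, n = 3) in the controls (exact permutation p = 0.518). Trbv16 and Trav6-1 led in the healthy thymus too, so a large share of either is not by itself a sign of a clone.

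**Figure D3:**
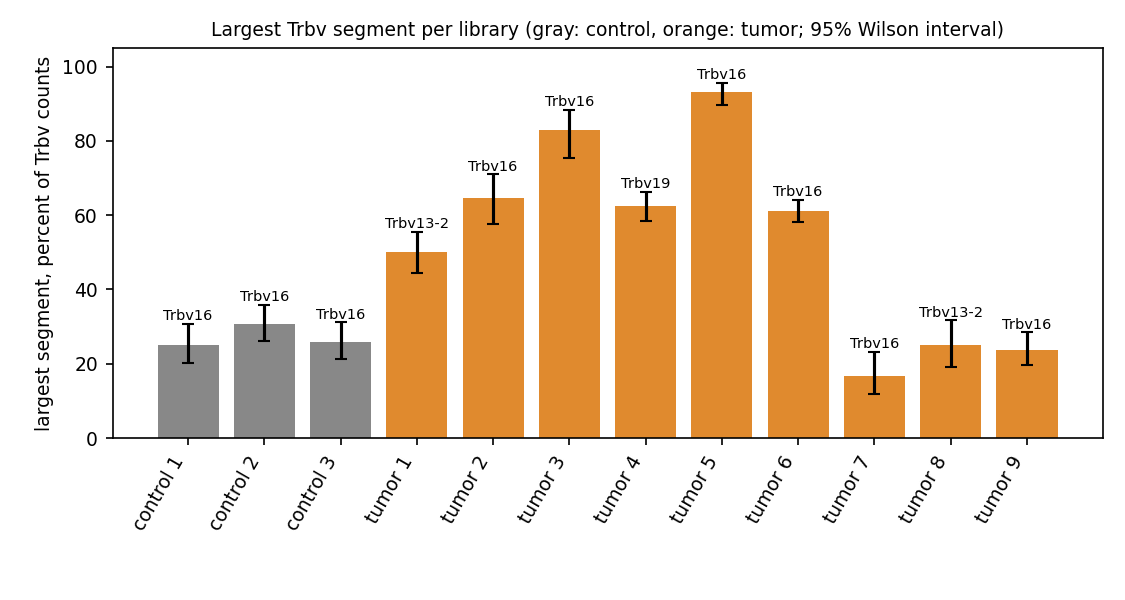
Bars show the percentage of Trbv counts on the largest Trbv segment of each library, named above the bar, with 95% Wilson intervals as error bars. Tumors 1 to 6 lie between 50.04% and 93.2%, tumors 7 to 9 between 16.6% and 24.9%, and controls between 25.1% and 30.8%.

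By camera, genes on chromosomes 15, 18, 19 and Y rose (adjusted p = 0.00738, 0.0222, 0.0275 and 0.00738) with medians of -0.06, -0.15, -0.04 and 0.22, above the median of -0.45 of all genes. Genes on the X chromosome fell, with a median of -0.88 (adjusted p = 0.00738). None of these calls held under the stricter filter, and that of chromosome 19 did not hold with library totals (adjusted p = 0.103). The sex chromosomes differed among the controls and between the tumors. Median log2 ratios to the controls, or of a control to the 2 others, for chromosome Y were -0.85, -0.82 and 1.65 in controls 1 to 3, -0.63 to -0.19 in tumors 1 to 6 and 0.92 to 1.46 in tumors 7 to 9. For chromosome X they were 0.08, 0.32 and -0.41 in the controls and below 0 in all tumors. Most autosomes were also below 0 in tumors 1 to 6. In tumors 1 and 2 chromosome X had -0.12 and -0.20, against -0.20 and -0.23 for chromosome 1, so X was not low there. In tumors 7 to 9 chromosome X had -0.33 to -0.26, against -0.0084 to 0.066 for chromosome 1. The calls on X and Y thus mix the sex of the mice and the background with the groups. Without tumors 7 to 9, chromosomes 11, 15, 18 and 19 rose and none fell. The median standard deviation of log2 CPM per gene was 1.22 over the 9 tumors and 0.279 over the controls. On log2(TPM + 1) it was 0.642 and 0.295, and 0.202 over tumors 1 to 6, below the controls. On the first principal component, with 67.4% of the variance, controls and tumors 7 to 9 lay between -213 and -179 and tumors 1 to 6 between 47.6 and 352. The closest pair of libraries, controls 2 and 3, had a chi-square of 3.29 per degree of freedom against counting error alone, which separate samples exceed by their nature.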

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

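The weighing tests in this part, the count of other splits of the libraries, the background measures and the 4 added alternatives were chosen after the results were seen, and the search for single tumors far from the others was fixed before.

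Of the 79 named genes, 14 had a single tumor beyond Dixon's critical value for 9 samples. In each case this tumor was the highest of the 9. Chance flags about 1 in 20 groups of normally distributed values. That rate need not hold for CPM over tumors of low and high background together, so the number is a description only. Tumor 6 was highest for Notch1 (809 CPM), Txnip (334), Jun (482) and Rag1 (65.2). Tumor 4 was highest for Hspa1b (312 CPM), Ighm (266) and Igkc (133). Tumor 2 was highest for Il2ra (70.9 CPM), Lyz2 (112) and S100a9 (105.3). Tumor 1 was highest for Lmo2 (11.7 CPM), tumor 5 for Rora (27.7), tumor 3 for Kmt2d (1003) and tumor 8 for Tigit (32.8). The number was 24 with RLE factors, 32 with TPM and 11 to 17 when a tumor was left out.

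The controls and tumors 7 to 9 shared a profile of satellite-like counts and evenly spread low counts apart from tumors 1 to 6. Receptor genes held 0.186% to 0.346% of the counts in tumors 1 to 6 and 1.44% to 3.84% in those 6 libraries, shares that a lower number of counts changes only by counting error. A shared cell state would need messenger RNA far above never-expressed genes, yet ribosomal protein genes had at most 7.75 times the density of the receptor genes in the 6 libraries and at least 190 times in tumors 1 to 4 and 6. Genomic DNA in these libraries is a candidate explanation that stays open: in the 4 of them with counts of Zfy1, a Y-linked gene restricted to testis, X-linked genes had 0.475 to 0.575 times the density of autosomal genes, as for a single X copy, and in the 2 without they had 0.764 and 0.98. Genomic DNA would also bring the receptor genes near the coding genes. Their median density was 0.674 to 0.910 times that of nuclear protein-coding genes in the 6 libraries, and 0 to 0.355 times in tumors 1 to 6. The explanation rests on 6 libraries, and counts beyond a DNA background remain, such as Ptprc in control 1, with 1034 counts over 336 of background.

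Il7r and T cell genes lay above the controls in tumors 1 to 6. Low messenger RNA signal in the control libraries may account for much of this, since ribosomal protein genes, which every cell expresses, had a median log2 fold change of 3.80 between the same libraries, against 4.14 for T cell identity and 5.56 for Il7r. Il7r induced in the tumors, the biological explanation that the design names, was tested by its ratio to Ptprc in control 1, where 76 Il7r counts against a background of 89.9 allow a ratio of at most 0.00755. That ratio was 0.0425 in tumor 6 to 0.610 in tumor 2. The 2 explanations cannot be told apart. Ptprc rose above the background in 1 control only, and that background was taken from controls 2 and 3, which may also hold RNA. Trbc2, chosen after its values were seen, lay there at 11.3 and 13.6 times the receptor genes. Whether RNA gave these Trbc2 counts was not tested.

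For the 2 genes called by edgeR between tumors and controls, 3 of 60 splits of the 12 libraries into 9 and 3, the real one included, called as many. The highest other split called 10 genes, with tumors 2, 5 and 6 as the 3, and the next 5, with tumors 1, 2 and 6. Both set tumors of low background against a group that holds all 6 libraries of high background, so they follow a structure of the samples, and the number of genes called does not exclude chance. The splits do not test Gm3147 and A430089I19Rik themselves, which had 45 to 103 counts in the controls and 0 or 1 in each tumor.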

How the results depend on the processing

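The 4 settings built on the background (without tumors 7 to 9, these tumors against the controls, the background as a covariate, and nuclear protein-coding genes with a name) and the scalings of the differences among tumors were chosen after the data were seen. The cause of the changes below was not tested, except where fewer libraries or genes enter by construction. RLE factors, library totals, no low-count filter, the stricter filter, length offsets and protein-coding genes only gave the same 2 lower genes, and edgeR gave 0 higher in each, with 4639 to 8155 genes at an unadjusted p below 0.05. DESeq2 called 4084 genes higher and 53 lower, of which 4084 and 52 by at least 2-fold, with neither of the 2 genes among the 53, as it gave them no adjusted p. Limma on log2(TPM + 1) called 126 and 34628 (123 and 29051 by 2-fold), and on log2(TPM + 0.1) 118 and 33150, all by 2-fold. Voom weights per group gave 6914 and 8111 (6696 and 7997 by 2-fold). Without tumors 7 to 9 there were 7562 and 7823 (7485 and 7714 by 2-fold), and in tumors 7 to 9 against the controls 9 and 9, all by 2-fold. With the background as a covariate, and among nuclear protein-coding genes with a name, edgeR called 0 genes in either direction, with 1265 and 4038 at an unadjusted p below 0.05. Leaving out 1 library gave 0 genes higher by edgeR throughout and 0 to 3 lower, both over all sizes and by 2-fold. The replicate numbers of the 3 controls and tumors 1 to 3 did not pair them, as same-numbered libraries had correlations of deviations of 0.0656, 0.0841 and -0.0939. With the replicate block on these 6 libraries there were 8091 higher and 1827 lower genes (8081 and 1822 by 2-fold), against 8717 and 3565 (8607 and 3387) in the same libraries unblocked.

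The log2 fold change of Il7r kept its sign in every setting and passed with DESeq2 (4.79), voom weights (4.02), the replicate block (6.30), the same 6 libraries unblocked (6.67) and without tumors 7 to 9 (5.56). Over single libraries left out it was 4.70 to 5.57 with adjusted p of 0.0602 to 0.531. Its difference by exact permutation was 1.74 with library totals and 1.03 on log2(TPM + 1), neither past the threshold, and 3.10 to 3.90 with 1 library left out, where it did not pass without control 1, 2 or 3. The number of rising lists was 12 among protein-coding genes and 11 among those with a name, with 2 falling in each. It was 16 with library totals, 15 on log2(TPM + 1), 14 on log2(TPM + 0.1), 18 with the stricter filter and without tumors 7 to 9, and 19 with DESeq2, RLE factors, voom weights and the same 6 libraries unblocked, with 0 falling in each. On log2(TPM + 1) oncogenes and sex-linked transcripts were among the 15. It was 4 with 1 falling in tumors 7 to 9 against the controls, 2 with 5 falling with the background as a covariate, 0 with an estimated correlation and 19 to 20 with 1 library left out. Chromosomes that rose and fell numbered 0 and 0 with the stricter filter, and 1 and 2 in tumors 7 to 9 against the controls, and 0 fell without tumors 7 to 9. The Trbv difference was 41.8 percentage points without tumors 7 to 9 and 21.0 to 30.6 with 1 library left out, and the Trav difference 4.30 to 13.2. The median standard deviation over tumors was 0.642 on log2(TPM + 1), where the controls had 0.295. Without tumors 7 to 9 it was 0.984 on log2 CPM and 0.202, below the controls, on log2(TPM + 1). Tumors standing apart numbered 24 with RLE factors and 32 with TPM. Of the 78 named genes other than Il7r, 23 kept their direction in all settings and 55 did not. Depth limits genes near the floor of 3 counts, which was 0.25 to 0.369 CPM in the controls before scaling.

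With the background as a covariate, log2 fold changes turned sign to -0.065 for Mcl1, -0.47 for Sesn3, -0.012 for Txnip, -0.063 for Npm1, -0.064 for Uhrf1, -0.032 for Top2a, -0.24 for Bcl2l11, -0.85 for Gapdh, -1.13 for Ldha, -0.39 for Scd2, -0.37 for Mx1, -0.019 for Satb1, 0.62 for Cd34 and 1.06 for Zeb2. They were also -0.27 for Tox, 1.04 for Tigit, 0.70 for Cxcr2, 0.29 for Epb42, -0.48 for Ccl25, 0.44 for Vwf, 0.71 for Plin1, -0.070 for Rora, -0.17 for Notch3, 0.014 for Cish, 0.66 for Socs2, 0.30 for Rag2, -0.57 for Cd4 and -0.26 for Cd8a. With the background as a covariate, where the median of all genes was 0.36, list directions relative to the other genes turned, with medians of 0.047 for PI3K parts, 0.27 for FOXO, 0.023 for MYC, -0.067 for G1-S, -0.14 for G2-M, 0.28 for BCL2 family, -0.45 for glycolysis and -0.13 for cholesterol. Such medians were also 0.092 for ATF4, -0.022 for double-positive, 0.77 for early progenitor, 0.067 for regulatory T cell, 0.54 for B cell, 0.62 for endothelial, 0.49 for adipocyte and 0.69 for NK cell. With limma on log2(TPM + 1), log2 fold changes took the other sign at -2.20 for Sesn3, -0.43 for Notch1, -1.07 for Rrm1, -0.19 for Trp53inp1, -0.35 for Mdm2, -1.04 for Bcl2l11, -0.91 for Gapdh, -0.78 for Ldha, -1.17 for Acaca, -0.63 for Mx1, -2.06 for Itga4 and -1.35 for Il2ra. They were also -0.41 for Tox, -0.23 for Igkc, -1.41 for Itgam, -0.71 for H2-Aa, -0.20 for S100a9, -0.76 for Tbata, -1.06 for Ccl25, -1.02 for Col1a2, -1.75 for Lipe, -0.053 for Gata3, -1.78 for Rora and -0.67 for Xist. Next came -0.98 for Uty, -1.28 for Lmo2, -0.61 for Notch3, -0.50 for Jak3, -1.02 for Stat5a, -1.20 for Bcl2, -0.48 for Pim1, -0.56 for Hes1, -0.52 for Cdkn2a, -0.44 for Rag1, -0.60 for Cd4 and -0.93 for Cd8a. With limma on log2(TPM + 1), list directions turned, with medians of -1.38 for regulatory T cell and -1.09 for thymic epithelium. With limma on log2(TPM + 0.1), log2 fold changes switched sign to -0.10 for Rictor, -2.41 for Sesn3, -0.53 for Notch1, -1.11 for Rrm1, -0.031 for Uhrf1, -0.31 for Trp53inp1, -0.43 for Mdm2, -1.29 for Bcl2l11, -0.94 for Gapdh, -0.82 for Ldha, -1.32 for Acaca, -1.09 for Mx1 and -2.43 for Itga4. They were also -1.97 for Il2ra, -0.51 for Tox, -1.25 for Igkc, -2.14 for Itgam, -0.92 for H2-Aa, -0.56 for S100a9, -0.87 for Tbata, -1.28 for Ccl25, -1.22 for Col1a2, -2.23 for Lipe, -0.10 for Gata3, -2.50 for Rora and -1.74 for Xist. Next came -1.11 for Uty, -0.020 for Bmi1, -2.25 for Lmo2, -1.51 for Notch3, -0.75 for Jak3, -1.28 for Stat5a, -1.94 for Bcl2, -0.91 for Pim1, -1.33 for Hes1, -1.16 for Cdkn2a, -1.28 for Rag1, -0.80 for Cd4 and -1.10 for Cd8a. With limma on log2(TPM + 0.1), list directions turned, with medians of -2.59 for thymic epithelium. In tumors 7 to 9 against the controls, log2 fold changes had the opposite sign at -0.45 for Sesn3, -0.021 for Uhrf1, -0.074 for Bcl2l11, -1.13 for Gapdh, -1.07 for Ldha, -0.22 for Scd2, 0.080 for Cd34, 0.56 for Zeb2, -0.084 for Tox and 0.33 for Tigit. They were also 0.14 for Cxcr2, 0.0080 for Epb42, -0.27 for Ccl25, 0.19 for Plin1, -1.25 for Xist, -0.35 for Notch3, 0.45 for Socs2, 0.16 for Rag2, -0.034 for Cd4 and -0.030 for Cd8a. In tumors 7 to 9 against the controls, list directions turned, with medians of -0.0089 for PI3K parts, -0.12 for G1-S, -0.011 for G2-M, -0.52 for glycolysis, -0.20 for cholesterol and -0.025 for ATF4. Such medians were also 0.12 for early progenitor, -0.30 for regulatory T cell, -0.024 for B cell, -0.028 for endothelial and -0.028 for NK cell. With library totals, log2 fold changes changed sign to -1.20 for Sesn3, -0.61 for Rrm1, -0.60 for Bcl2l11, -0.58 for Acaca, -1.56 for Itga4, -0.73 for Il2ra, -1.16 for Itgam, -0.12 for Tbata and -0.52 for Ccl25. They were also -0.53 for Lipe, -1.21 for Rora, -0.82 for Lmo2, -0.10 for Notch3, -0.24 for Jak3, -1.07 for Bcl2, -0.20 for Pim1, -0.36 for Cdkn2a and -0.12 for Cd8a. With library totals, list directions turned, with medians of -1.56 for thymic epithelium. Among nuclear protein-coding genes with a name, log2 fold changes crossed 0 to -0.44 for Itga4 and -0.10 for Rora. Among nuclear protein-coding genes with a name, list directions turned, with medians of -0.47 for oncogene, -0.40 for cytotoxic, -0.42 for inhibitory receptor, -0.43 for regulatory T cell, -0.60 for dendritic cell, -0.20 for neutrophil, -0.71 for thymic epithelium and -0.34 for fibroblast. Among protein-coding genes, log2 fold changes turned sign to -0.29 for Itga4. Among protein-coding genes, list directions turned, with medians of -0.36 for oncogene, -0.26 for cytotoxic, -0.25 for inhibitory receptor, -0.23 for regulatory T cell, -0.032 for neutrophil, -0.57 for thymic epithelium and -0.19 for fibroblast. With the stricter filter, Itga4 had -0.078 and the lists of neutrophils and thymic epithelium turned, with medians of -0.38 and -0.45. Itga4 also turned with DESeq2, RLE factors and the fit without tumors 7 to 9, at -0.21 in each, and Xist with DESeq2, at -1.44. Zeb2 turned to 0.23 with length offsets, 0.021 with the replicate block and 0.046 in the same 6 libraries unblocked. The neutrophil list turned with voom weights, with a median of -0.67, and thymic epithelium without tumors 7 to 9, with -0.81. Leaving out 1 library gave -0.14 to 0.26 for Itga4, which turned without each control, tumor 8 or tumor 9, and -0.39 to 0.094 for Zeb2, which turned without tumor 4, 5 or 6. The cytotoxic list, with medians of -0.12 to 0.25, turned without tumor 4. The NK list, with -0.72 to -0.30, turned without tumor 1 or 6, and the neutrophil list, with -0.41 to 0.52, without tumor 2. No named gene had passed the threshold, so no call of a gene was undone. With limma on log2(TPM + 1), 8 of the turned genes passed as lower, with adjusted p of 0.00646 for Sesn3, 0.00843 for Itga4, 0.0471 for Il2ra, 0.00811 for Itgam, 0.00773 for Lipe, 0.00445 for Rora, 0.0286 for Lmo2 and 0.0167 for Bcl2. On log2(TPM + 0.1) these passed too, except Il2ra. Calls of rising lists were undone. With the background as a covariate glycolysis (adjusted p = 4.02e-07), G2-M (3.73e-04), G1-S and cholesterol (0.00536 each) and PI3K parts (0.0120) passed as falling relative to all genes, whose median was 0.36 there, and early progenitors (0.00444) turned to rising. Glycolysis also fell in tumors 7 to 9 against the controls (3.24e-04).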

Other observations

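The genes in this part were chosen after their values were seen, except Igkc, S100a9, Xist, Cxcr2 and Uty. All tests reported here were chosen after the result was seen.

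A few genes of other blood cells stood out in single tumors. In tumor 4, Igkc, an immunoglobulin light chain of plasma cells, was at 133 CPM against at most 2.46 CPM in the 8 other tumors, and Jchain, which joins antibody units, was at 31.9 CPM against 0.96 to 6.77 CPM in tumors 1, 2, 3, 5 and 6, 11.3 to 19.1 in tumors 7 to 9 and 7.17 to 11 in the controls. In tumor 2, the neutrophil genes S100a8, S100a9 and Ngp were at 88.1, 105.3 and 53.5 CPM, against at most 6.95, 6.54 and 6.27 CPM in the other tumors. Cxcr2, also a neutrophil gene, did not stand out there, at 22.1 CPM against 21.9 CPM in tumor 1 and 26.4 to 28.5 CPM in the controls, and no test of neutrophils was made for tumor 2. Xist, expressed from the inactive X chromosome, was at 1056 CPM in tumor 1, 838 in tumor 2 and 1.78 to 8.21 in tumors 3 to 9. Y-linked genes did not go together. Ddx3y was at 80.5 and 73.3 CPM in tumors 3 and 4 and 1.66 CPM in tumor 6, and Eif2s3y at 1.48, 59.7 and 64.5 CPM in tumors 3, 4 and 6. Uty was at 158 CPM in tumor 1, where Xist was highest, and 114.5, 108 and 69.4 CPM in tumors 3, 4 and 6. In tumor 5, Xist was at 7.66 CPM, Ddx3y at 0.439 CPM and Eif2s3y at 0.16 CPM.

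A few loci differed between all or nearly all tumors and the controls, tumors 7 to 9 included. Skint9 (chromosome 4, 112385969 to 112433985) had 20 to 32 counts in the controls and 0 counts in the 9 tumors. Gm42661, near Gm3147 and A430089I19Rik on chromosome 5 at 95063576, had 28 to 65 counts in the controls, 5 counts in tumor 2 and 0 in the 8 others. Gvin1 (chromosome 7, from 106156556), a large interferon-induced GTPase gene, had 1, 0 and 0 counts in the controls, 0 counts in tumor 3 and 16 to 329 counts in the other tumors. These 3 genes were among the 18 called by edgeR between tumors 7 to 9 and the controls, with adjusted p of 0.0445, 0.0371 and 0.00132. A difference in genetic background between the control and tumor mice would give such counts without a change in expression, and it was not tested. In the controls, where most coding genes lay near the receptor genes, Trbv16 lay 8.79 to 15.4 times, and Trav6-1 34.3 to 40.3 times, above the median density of the receptor genes. A rearranged receptor transgene in these mice is a hypothesis for both segments that was not tested, and with it a large share of either segment would not mark a clone.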
